A study of Mus musculus with 6 samples.

How the data were processed

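Total RNA from mouse embryonic stem cells was extracted with Trizol and made into libraries with the Illumina TruSeq RNA kit, and per the series' design text these were sequenced on a Novaseq6000. The 6 libraries were placed in 2 groups by their titles, 3 control (Rbbp4F/F) and 3 knockout. The labels do not say whether the libraries of a group came from separate cultures or cell lines, so p-values measure only the spread between these libraries, which is possibly technical.

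Each deposited file holds a gene identifier and a value per gene, without a header. The submitters' processing notes name FastQC, HISAT2 2.1.0, RSEM, DESeq 1.26.0 and the genome build GRCm38.p6, without roles. The annotation release, the mapping options and whether strand was used in counting are not given in the sources used here, so antisense overlap is named in the results for some genes. It is not named there for every gene. Antisense exons also cover 18.2% of Bak1, 17.2% of Rps25, 11.5% of Gpi1, 7.7% of Cdkn1a and 6% of Rbbp7, and smaller shares of others. The unit of the values the authors deposited was taken to be FPKM from the values themselves. They are not whole numbers, they sum to 697933 to 800146 per library where TPM would give one sum for all, and after multiplication by transcript length in kb their sums lie closer together, at 894119 to 945245. FPKM divides by transcript length and by the total of assigned fragments, so a fall of abundant transcripts raises the values of the rest. Low values of transcripts of known length lie on even steps, and 86.9% to 90.3% of them fell within 0.15 of a whole step, which gave the depth estimates. Fragments per gene were not recovered from them, and no count model was used.

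Each file has 52872 rows. 2 rows per file hold overflowing text instead of a gene identifier and were left out. The other 52870 rows are 51912 Ensembl genes and 958 loci assembled from the reads. Symbols, coordinates, GC content and transcript lengths came from GENCODE release M21 on GRCm38, which matched 51719 Ensembl identifiers and left 193 without a symbol.

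Genes with at least 1 FPKM in at least 3 libraries were tested, 13579 in all, 12212 of them protein-coding. Values were compared as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend, group as the only term, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. Fold changes are on this log2 scale, knockout minus control, which understates the change of low genes, while means and ratios of means are in FPKM. The design written before the data were examined assumed counts and named limma on log2(value + 1) for a normalized unit, so the second was used. No replicate block was fitted in this test. The median SD between replicates over genes was 0.174 on the log2 scale. The test was tried on simulated data for 13579 genes with 200 changed. It recovered 64.2% of genes changed by 1.5-fold, 97.0% of those changed by 2-fold and 90.9% of those changed by 4-fold, where low values were bounded at 0, with 8 false calls, 4.5% of all calls. The simulation had independent noise and few changed genes, whereas 59.1% of tested genes were called in the data. Its rates therefore do not carry over to the calls reported here.

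25 gene lists and the rule for named genes were also fixed before the data were examined. The rule took Rbbp4 and its paralog Rbbp7, the factors Pou5f1, Sox2 and Nanog, the 8 largest and 8 smallest log2 fold changes among called genes whose groups did not overlap and whose mean was at least 1 FPKM (without predicted genes, pseudogenes, histone, mitochondrial and ribosomal protein genes), and up to 3 called members of each list with the smallest p, or the member with the smallest p where none was called. Values of some genes that these rules take are not reported here. Lists were compared with other genes by camera (limma) with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 24 lists with more than 1 tested gene. With a correlation estimated from these 6 libraries no list passed. In that setting camera also takes its degrees of freedom from the libraries instead of the number of genes. That no list passed therefore cannot be assigned to correlation alone. The fry test, which asks whether the genes of a list move one way on balance without comparing them with other genes, was run as an alternative. 8 further lists were chosen after the data were examined and appear only in the closing observations.

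Alternatives tried were median-ratio and upper-quartile scaling, totals without the 20 most abundant genes, a pseudocount of 0.1, no filter on low values, the replicate number as a block, each library left out in turn (with at least 1 FPKM in 2 libraries) and a 1.5-fold threshold inside the test. Rescaling to equal FPKM sums, a filter of 5 FPKM, a loess correction for GC content and transcript length, and protein-coding genes alone were added after the data were examined.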

Results

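Transcript levels were measured by RNA sequencing in mouse embryonic stem cells, the pluripotent cells that can be grown from the early embryo. The cells were of the C57BL/6 strain. 3 libraries came from Rbbp4F/F cells, named as the control in the series title, and 3 came from Rbbp4-/- cells, called the knockout here. Rbbp4 encodes a histone-binding protein shared by several chromatin complexes, among them Polycomb repressive complex 2, NuRD, Sin3 and the histone chaperone CAF-1. The comparison asked which transcripts differ between cells with and without the gene. Values are FPKM, fragments scaled by transcript length and by the total of fragments, and each mean is given ± SD with n = 3 libraries per group. The spacing of low values gave an estimated depth of 25600000 to 29200000 fragments per library. At that depth 1 fragment on a transcript of 2 kb is worth 0.0171 to 0.0195 FPKM.

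The targeted gene separated the groups. Rbbp4 (ENSMUSG00000057236, GRCm38 chromosome 4, 129307100 to 129335370, minus strand, 11 exonic blocks) had 58.5, 57.0 and 61.8 FPKM in control replicates 1 to 3. In knockout replicates 1 to 3 it had 21.3, 12.7 and 11.1 FPKM. The mean fell from 59.1 ± 2.44 to 15.03 ± 5.47 FPKM, a log2 fold change of −1.96 (SE 0.22, limma adjusted p = 3.94e-04), which left 25.5% of the control level. The labels do not give the deleted exons and the value covers the whole gene, so the remaining signal cannot be assigned to a part of the transcript. Exons of an antisense gene, Gm26722, overlap 9.1% of the exonic length. Rbbp7, the paralog of Rbbp4, had 175.6 ± 0.497 FPKM in the controls and 241 ± 38.4 FPKM in the knockout libraries, a log2 fold change of 0.44 (SE 0.12, limma adjusted p = 0.0169). The call of the Rbbp7 log2 fold change was lost with median-ratio scaling (0.28, limma adjusted p = 0.0866), with upper-quartile scaling (0.18, limma adjusted p = 0.235) and when control replicate 1 (0.0552), 2 (0.0534) or 3 (0.0524) or knockout replicate 2 (0.0640) or 3 (0.0503) was left out, and its limma adjusted p ran from 2.15e-04 to 0.235 over all alternatives.

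The change in the transcriptome was broad. Of 13579 genes tested, 4978 were higher and 3051 were lower in the knockout libraries, and 1821 and 967 of these changed by at least 2-fold. In 5606 genes every knockout library lay above every control library, and in 3464 every one lay below, where chance would give 10% of genes in both directions together. With median-ratio scaling between libraries the split was 3994 higher and 3844 lower, with upper-quartile scaling 3453 and 4402, and with each library rescaled to an equal FPKM sum 6080 and 2380. The median log2 fold change of all tested genes was 0.17 with the values as deposited and 0.02 with median-ratio scaling. It was −0.07 with upper-quartile scaling and 0.31 with equal sums. List medians in the text are therefore given relative to all tested genes, except where a median log2 fold change is named. Knockout replicate 1, which held the most Rbbp4 transcript of the knockout libraries, stood apart on the second principal component, at 36 against −7 and −24.2 for replicates 2 and 3. Without it, 5592 genes were higher and 3587 lower.

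**Figure D1:**
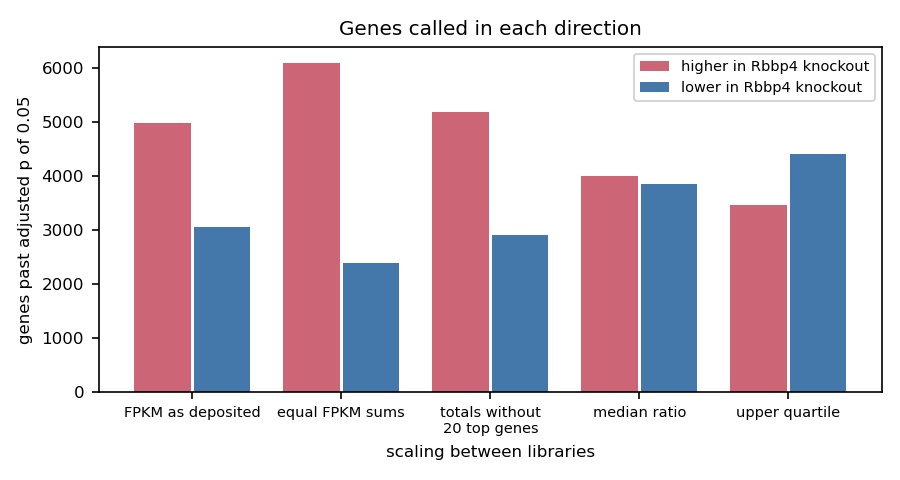
Number of genes past an adjusted p of 0.05 (vertical axis) that were higher or lower in the knockout libraries, for 5 ways of scaling between libraries (horizontal axis). With the deposited FPKM 4978 genes were higher and 3051 lower; with upper-quartile scaling the larger side turned, to 3453 higher and 4402 lower.

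The 8 genes with the largest increase included a stress-inducible growth arrest gene, keratin genes and genes of the cytoskeleton and extracellular matrix. Gadd45g rose from 4.44 ± 0.530 to 160.6 ± 5.75 FPKM, a log2 fold change of 4.90 (SE 0.10, limma adjusted p = 4.72e-06). The keratin genes Krt18 and Krt8, which encode partners of the filaments of simple epithelia, rose from 55.5 ± 11.8 to 1575 ± 437 FPKM and from 65.8 ± 17.7 to 1586 ± 478 FPKM. The others were the small heat shock protein gene Cryab (log2 fold change 4.57), the galectin gene Lgals3 (4.25), the actin crosslinker gene Flnc (4.24), Trim17 (4.19) and the matrix glycoprotein gene Thbs1 (4.17). Exons of Hist3h2a on the same strand cover 19% of Trim17, and antisense exons of Hspb2 cover 17% of Cryab, and reads there cannot be told apart.

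The 8 genes with the largest decrease included Nanog, described with the pluripotency genes, and genes of growth factor signalling and metabolism. Igfbp2, which encodes a carrier of insulin-like growth factors, fell from 224 ± 30.0 to 7.32 ± 2.80 FPKM, a log2 fold change of −4.80 (SE 0.24, limma adjusted p = 3.40e-05). Pck2, the mitochondrial phosphoenolpyruvate carboxykinase gene, fell from 42.8 ± 4.99 to 1.14 ± 0.225 FPKM, and Pycr1, which encodes an enzyme of proline synthesis, from 46.7 ± 3.57 to 2.93 ± 0.936 FPKM. Log2 fold changes were −4.41 for the thyrotropin-releasing hormone gene Trh, −3.92 for Ifitm1, −3.37 for Ndufa4l2, which was listed at 0 in knockout replicate 2, and −3.36 for Enpp3.

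Pluripotency genes mostly fell. Of 15 core pluripotency genes, 11 fell and 3 rose, and the counts adjusted over the list alone were also 11 and 3. Nanog, a transcription factor of the pluripotent state, fell from 79.2 ± 5.31 to 4.31 ± 0.641 FPKM, an 18.4-fold difference in means (log2 fold change −3.92, SE 0.12, limma adjusted p = 1.33e-05). Pou5f1, which encodes Oct4, fell less, from 1113 ± 61.2 to 378 ± 111 FPKM (log2 fold change −1.59, SE 0.19, limma adjusted p = 5.44e-04). Sox2 fell from 166.5 ± 7.504 to 57.9 ± 4.84 FPKM (−1.51, SE 0.08, limma adjusted p = 4.27e-05), and Tdgf1, a coreceptor gene of Nodal signalling, from 437 ± 20.7 to 72.4 ± 4.10 FPKM. Relative to all tested genes the list median was −1.01 (camera adjusted p = 4.93e-04, and adjusted p = 0.209 with an estimated correlation). The 3 that rose, named after their values were seen, were Zfp281 (1.14), Dppa2 (0.46) and Sall4 (0.30). The Sall4 call was lost with median-ratio scaling, and the Dppa2 and Sall4 calls with upper-quartile scaling. Antisense exons of Gm19553 overlap 14.1% of Pou5f1.

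Among 18 genes of naive pluripotency, the state of the preimplantation embryo, 13 fell and 3 rose, with 13 and 3 adjusted over the list alone. Fgf4 fell from 107 ± 9.32 to 14.4 ± 1.36 FPKM, Jam2 from 22.0 ± 1.01 to 4.51 ± 0.262 FPKM and Nr0b1 from 65.2 ± 1.5 to 17.9 ± 3.25 FPKM. The list median was −1.19 relative to all tested genes (camera adjusted p = 2.82e-05, and adjusted p = 0.122 with an estimated correlation). Zfp42, the gene of the stem cell marker Rex1, had 35.1 ± 2.34 and 31.9 ± 2.57 FPKM (log2 fold change −0.13, limma adjusted p = 0.261), and it passed as lower with median-ratio scaling (−0.29) and upper-quartile scaling (−0.39). The 3 genes that rose were Klf4 (0.44), Klf5 (0.72) and Tbx3 (0.76), and the Klf4 call was lost with median-ratio scaling (0.31) and upper-quartile scaling (0.23). Zfp42 and these 3 genes were singled out after their values were seen.

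Genes of the formative and primed states, which follow naive pluripotency, fell as a list. Of 13 tested, 9 fell and 2 rose, and 9 and 2 passed when adjusted over the list alone. The transcription factor gene Tcf15 fell from 27.4 ± 7.91 to 3.49 ± 0.569 FPKM and the DNA methyltransferase gene Dnmt3a from 38.4 ± 3.22 to 13.2 ± 0.3004 FPKM, while the claudin gene Cldn6 rose from 88.8 ± 1.67 to 268 ± 14.7 FPKM. The other gene that rose, named after its value was seen, was Grhl2 (0.55), whose call was lost with upper-quartile scaling. The median relative to all tested genes was −0.96 (camera adjusted p = 4.93e-04, and adjusted p = 0.194 with an estimated correlation).

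**Figure D2:**
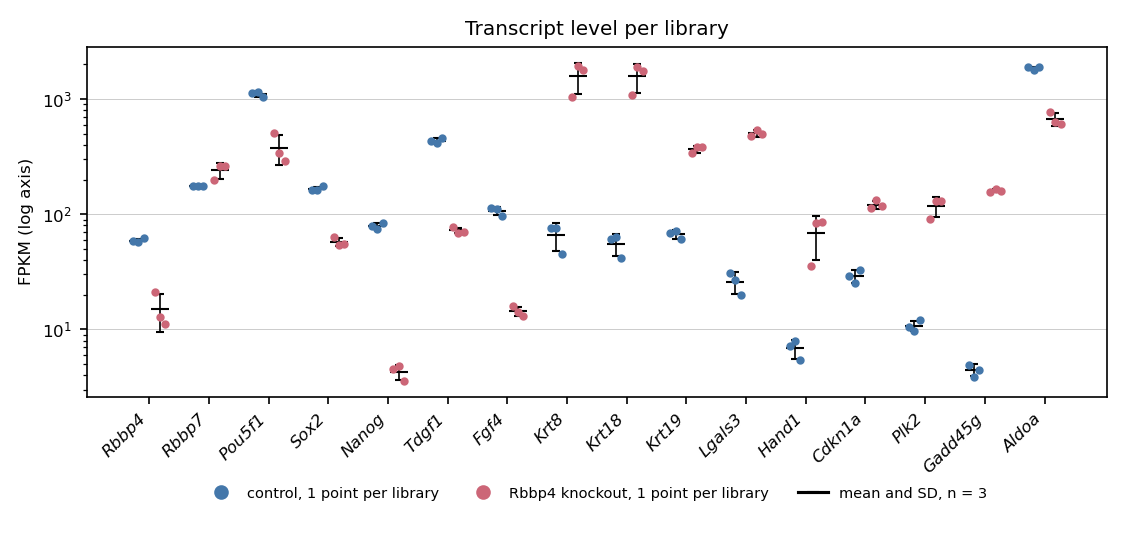
FPKM (log axis) of 16 genes in each of the 6 libraries, with the mean and SD of each group (n = 3). Nanog drops from 79.2 to 4.31 FPKM, further than Pou5f1 or Sox2, while Krt8 and Krt18 reach 1586 and 1575 FPKM in the knockout libraries.

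Trophoblast genes, markers of the lineage that forms the placenta, rose. Of 21 tested, 18 rose and 1 fell, with 18 and 1 adjusted over the list alone, and the median was 1.77 above that of all tested genes (camera adjusted p = 2.44e-05, and adjusted p = 0.287 with an estimated correlation). Besides Krt18 and Lgals3, which rose from 25.9 ± 5.46 to 505 ± 32.3 FPKM, Krt19 rose from 67.4 ± 5.91 to 369 ± 25.5 FPKM (log2 fold change 2.44, SE 0.09, limma adjusted p = 1.49e-05). The lineage transcription factor genes Cdx2 and Gata3, singled out after their values were seen, both rose. Cdx2 had 0, 0.12 and 0.06 FPKM in the controls and 1.4, 1.77 and 1.39 FPKM in the knockout libraries, and Gata3 rose from 0.603 ± 0.330 to 5.17 ± 1.34 FPKM. Another such factor gene, Elf5, also singled out afterwards, had 1.29 ± 0.497 and 1.99 ± 0.283 FPKM (limma adjusted p = 0.119), and the placental cadherin gene Cdh3, named for the same reason, was the 1 that fell, from 22.6 ± 1.87 to 10.8 ± 0.102 FPKM. The other member not called was Fgfr2 (log2 fold change −0.24, limma adjusted p = 0.577), likewise singled out afterwards. The call of Ascl2 (0.48), also named afterwards, was lost with median-ratio and upper-quartile scaling, where 17 rose. The number of risen trophoblast genes was also 17 without control replicate 1 or 3 or knockout replicate 2 or 3. The list shares Krt8, Krt18 and Cdh3 with the epithelial list and Hand1 with the mesoderm list.

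Markers of the germ layers moved in both directions. Of 8 mesoderm genes, 6 rose and 1 fell, and 6 and 1 passed when adjusted over the list alone. The cardiac and placental factor gene Hand1 rose from 6.84 ± 1.27 to 68.1 ± 28.4 FPKM, Gata2 from 1.93 ± 0.379 to 12.3 ± 1.64 FPKM and Nkx2-5 from 0.693 ± 0.0643 to 5.47 ± 0.336 FPKM. The mesoderm list did not pass (camera adjusted p = 0.0677), although it passed without control replicate 2 (0.0410) or control replicate 3 (0.0415), with median-ratio scaling (0.0372) and with upper-quartile scaling (0.0353), and its camera adjusted p ran from 0.0163 to 0.257 over all alternatives. The gene that fell, named after its value was seen, was Kdr (−0.75), and without a filter 10 of 24 genes were higher and 2 lower. The mesoderm gene not called, also named afterwards, was Eomes (log2 fold change 0, limma adjusted p = 0.984). Of 13 endoderm and primitive endoderm genes, 8 rose and 2 fell, with 8 and 3 adjusted over the list alone (camera adjusted p = 0.353), and without a filter 13 of 22 were higher and 2 lower (camera adjusted p = 0.0303). The receptor gene Lrp2 rose from 2.27 ± 0.334 to 18.2 ± 3.39 FPKM and Gata4 from 0.580 ± 0.104 to 3.31 ± 0.709 FPKM, while the laminin gene Lama1 fell from 23.1 ± 0.994 to 3.65 ± 1.42 FPKM.

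In the neuroectoderm list 4 of 11 genes rose and 6 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.144). Gbx2 fell from 43.0 ± 8.77 to 4.46 ± 0.786 FPKM and the neuronal tubulin gene Tubb3 from 149 ± 24.2 to 26.2 ± 3.02 FPKM, whereas the neural progenitor filament gene Nes rose from 6.44 ± 0.296 to 17.7 ± 0.707 FPKM. Others that rose, named after their values were seen, included Msx2 (1.73) and Pax3 (1.09), and Pax3 was below the filter with upper-quartile scaling. Without a filter the larger side turned, with 12 of 24 genes higher and 6 lower (camera adjusted p = 0.637). Antisense exons of D130058E05Rik overlap 43.5% of Gbx2. The number of risen genes was 7, 7 and 8 without control replicate 1, 2 or 3, and in each of these and without knockout replicate 1 more genes of the list were tested and its median log2 fold change turned positive (0.15 to 0.65). Without knockout replicate 1 the list's 0.15 still lay below the median of all tested genes, 0.172.

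Of 39 Hox genes, 5 passed the filter, each through the knockout libraries alone, so the filter admitted them because they were higher there. These 5 rose, also when adjusted over the list alone (camera adjusted p = 0.00900, and adjusted p = 0.194 with an estimated correlation). Hoxc13 rose from 0.263 ± 0.0802 to 2.60 ± 0.110 FPKM and Hoxa7 from 0.227 ± 0.0666 to 2.11 ± 0.384 FPKM, although antisense exons overlap 20.4% of Hoxa7. Other members, named after their values were seen, included Hoxb9 (1.29) and Hoxd9 (1.01), and at an unadjusted p under 0.05 in limma 5 were higher and 0 lower. Without a filter on low values, 23 of 38 Hox genes were higher and 0 lower (camera adjusted p = 2.10e-07), or 30 and 0 at an unadjusted p under 0.05 in limma. Of 16 germline genes, 12 rose and 2 fell, with 13 and 2 adjusted over the list alone, and without a filter 15 of 24 were higher and 2 lower (camera adjusted p with the filter = 0.00564, and adjusted p = 0.287 with an estimated correlation). Taf7l, a testis-specific general transcription factor gene, rose from 0.713 ± 0.215 to 18.0 ± 2.63 FPKM, the RNA helicase gene Ddx4 from 6.31 ± 0.432 to 27.7 ± 5.73 FPKM and the synaptonemal complex gene Sycp1 from 0.690 ± 0.106 to 3.33 ± 0.473 FPKM. The 2 that fell, named after their values were seen, were Stra8 (−1.02) and Rpl10l (−0.68). Of 27 markers of the 2-cell-like state 26 stayed below the filter, at up to 0.510 FPKM, and 14 were listed at 0 in all 6 libraries. The member tested, Cphx1, had 2.58, 1.87 and 0 FPKM in the controls and 1.65, 0.09 and 1.78 FPKM in the knockout libraries (limma adjusted p = 0.869) and made no call adjusted over the list alone. Without a filter 13 of these markers were tested, of which 0 were higher and 0 lower, also at an unadjusted p under 0.05 in limma (camera adjusted p = 0.678). Many of these genes have near-identical copies, among which reads cannot be divided with certainty.

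Proliferation genes fell by smaller amounts. Of 28 S phase genes, 19 fell and none rose, with 19 and 0 adjusted over the list alone. Uhrf1, which encodes a cofactor of maintenance DNA methylation, fell from 181 ± 4.22 to 83.3 ± 9.87 FPKM, the replication licensing gene Cdc6 from 55.2 ± 3.54 to 26.4 ± 1.21 FPKM and the ribonucleotide reductase gene Rrm2 from 169.7 ± 6.18 to 86.8 ± 9.35 FPKM. The median was −0.70 relative to all tested genes (camera adjusted p = 4.43e-06, and adjusted p = 0.122 with an estimated correlation). At an unadjusted p under 0.05 in limma 1 was higher and 19 lower, and 2 rose without knockout replicate 1 and 1 without knockout replicate 3. Of 28 genes of G2 and mitosis, 16 fell and 1 rose, again 16 and 1 adjusted over the list alone (camera adjusted p = 2.44e-05, and adjusted p = 0.122 with an estimated correlation). Topoisomerase gene Top2a fell from 224 ± 3.28 to 92.5 ± 7.82 FPKM, and the cyclin genes Ccnb2 and Ccnb1 fell from 129.7 ± 4.40 to 61.3 ± 2.996 FPKM and from 199 ± 2.48 to 104 ± 3.595 FPKM. The 1 gene that rose was Foxm1 (log2 fold change 1.22), named after its value was seen, and with equal FPKM sums 3 rose and 13 fell.

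Targets of p53 and inhibitors of cyclin-dependent kinases rose. Of 26 tested, 20 rose and 2 fell, with 20 and 2 adjusted over the list alone, and the median was 0.80 above that of all tested genes (camera adjusted p = 2.38e-04, and adjusted p = 0.204 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 29.0 ± 3.71 to 121 ± 10.1 FPKM (log2 fold change 2.03, SE 0.11, limma adjusted p = 4.38e-05). Plk2 rose from 10.8 ± 1.15 to 117 ± 23.0 FPKM and Phlda3 from 45.4 ± 1.41 to 171 ± 15.3 FPKM. The 2 that fell, named after their values were seen, were Sesn1 (−0.95) and Cdkn1c (−0.62), and 1 fell without control replicate 1, 2 or 3 and with equal FPKM sums. Apoptosis genes as a list did not differ from other genes beyond the threshold (camera adjusted p = 0.572), and 11 of 25 rose and 3 fell, with 11 and 3 adjusted over the list alone. The survival gene Bcl2l1 rose from 43.6 ± 3.73 to 94.2 ± 4.07 FPKM, and the death effector genes Bak1 and Casp8 rose from 45.5 ± 3.07 to 70.9 ± 2.91 FPKM and from 0.943 ± 0.369 to 3.87 ± 0.718 FPKM. The number of risen apoptosis genes was 6 without control replicate 1, 6 without control replicate 2 and 7 without knockout replicate 2, and that of fallen genes (among them Bmf and Bok, named after their values were seen) was 1 without control replicate 1 and 5 without knockout replicate 1. With median-ratio scaling 8 rose and 5 fell, and with upper-quartile scaling 6 rose and 6 fell, while with equal FPKM sums 2 fell and the Bok call was lost.

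Genes of the complexes that contain Rbbp4 changed in both directions, as did the tested genes at large, of which 59.1% were called. Of 12 genes of Polycomb repressive complex 2, 3 rose and 3 fell, and the same numbers passed when adjusted over the list alone (camera adjusted p = 0.258). The methyltransferase gene Ezh2 fell from 62.2 ± 4.003 to 37.7 ± 1.31 FPKM, and the accessory genes Epop and Jarid2 fell from 343 ± 66.3 to 165 ± 6.77 FPKM and from 165 ± 9.71 to 79.8 ± 19.1 FPKM. The 3 that rose were Rbbp7, Aebp2 (0.80) and Phf1 (0.49), the last pair named after their values were seen. The number that rose was 1 without control replicate 1, 2 or 3 or knockout replicate 3, and with median-ratio and upper-quartile scaling 1 gene rose and 4 and 6 fell. With the GC and length correction 3 rose and 5 fell. Of 32 partners in NuRD, Sin3, CAF-1, NURF, MuvB and Hat1 complexes, 10 rose and 12 fell, with 10 and 12 adjusted over the list alone (camera adjusted p = 0.472). With equal FPKM sums 14 rose and 9 fell. The remodeller gene Chd3 rose from 3.06 ± 0.395 to 23.2 ± 2.70 FPKM and Mbd2, which encodes a reader of methylated DNA, from 10.03 ± 1.39 to 28.9 ± 5.72 FPKM. The scaffold gene Sin3a fell from 68.9 ± 3.15 to 28.2 ± 4.39 FPKM. The median and the mean log2 fold change of this list were above 0 (0.10 and 0.07), while the direction of the camera test, which compares it with other genes, was down.

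Imprinted genes, expressed from 1 parental allele, did not differ from other genes beyond the threshold as a list (camera adjusted p = 0.875), and 11 of 24 rose and 5 fell, with 11 and 5 adjusted over the list alone. Sgce rose from 3.78 ± 0.1997 to 14.2 ± 1.35 FPKM and the amino acid transporter gene Slc38a4 from 40.6 ± 1.94 to 82.8 ± 5.48 FPKM, while Phlda2 fell from 294 ± 25.6 to 92.2 ± 8.44 FPKM. The others that fell, named after their values were seen, were Nnat (−1.06), Cdkn1c (−0.62), Grb10 (−0.54) and Rian (−0.45), and the calls of Cdkn1c and Rian were lost with equal FPKM sums, where 3 fell. The number of risen imprinted genes was 7 without knockout replicate 2. With median-ratio scaling 7 rose and 8 fell, and with upper-quartile scaling 7 rose and 9 fell, so the larger side turned.

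Adhesion and matrix genes held both large increases and large decreases. Of 19 epithelial genes, 12 rose and 4 fell, with 12 and 4 adjusted over the list alone (camera adjusted p = 0.0614). Besides the keratins, the claudin gene Cldn7 rose from 54.4 ± 2.66 to 124 ± 6.96 FPKM. The epithelial list passed without control replicate 2 (0.0499) or knockout replicate 1 (0.0339), with median-ratio scaling (0.0387) and with upper-quartile scaling (0.0334), and its camera adjusted p ran from 0.0147 to 0.479 over all alternatives. The 4 that fell, named after their values were seen, were Tjp3 (−1.93), Cdh3 (−1.0), Epcam (−0.82) and Esrp1 (−0.36), and the Esrp1 call was lost with equal FPKM sums (−0.21). Of 18 extracellular matrix and mesenchymal genes, 12 rose and 3 fell, with 12 and 3 adjusted over the list alone (camera adjusted p = 0.114). Thbs1 rose from 1.63 ± 0.384 to 47.9 ± 15.3 FPKM and the matricellular gene Ccn1 from 28.8 ± 5.25 to 256 ± 29.5 FPKM, while the fibronectin gene Fn1 fell from 162 ± 22.4 to 36.04 ± 0.727 FPKM, as did Mmp2 (−2.08) and Itgb3 (−0.46), named after their values were seen. The Itgb3 call was lost with equal FPKM sums (−0.36).

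Fibroblast markers were included because stem cells are often grown on fibroblast feeder cells, although the labels do not mention feeders. Of 7 tested, 4 rose and 2 fell, with 4 and 2 adjusted over the list alone (camera adjusted p = 0.589). Ptx3 had 0.11, 0.02 and 0 FPKM in the controls and 3.63, 3.41 and 3.38 FPKM in the knockout libraries, S100a4 rose from 0.92 ± 0.03 to 3.56 ± 1.48 FPKM, and Thy1 fell from 14.8 ± 3.15 to 7.68 ± 0.382 FPKM. The others that passed, named after their values were seen, were Acta2 (1.77), Loxl1 (0.78) and Fbln2 (−1.0). Exons of another gene on the same strand cover 51.7% of S100a4. The collagen genes Col1a1, Col1a2 and Col3a1 stayed below 1 FPKM in all 6 libraries.

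Genes of glucose use and the hypoxia response fell. Of 23 tested, 20 fell and 1 rose, with 20 and 1 adjusted over the list alone, and the median was −1.31 relative to all tested genes (camera adjusted p = 2.58e-09, and adjusted p = 0.194 with an estimated correlation). The glycolytic enzyme gene Aldoa fell from 1851 ± 59.0 to 667 ± 87.5 FPKM (log2 fold change −1.48, SE 0.11, limma adjusted p = 8.10e-05), Pfkp from 42.2 ± 1.53 to 7.58 ± 1.52 FPKM and Gpi1 from 322 ± 6.72 to 161 ± 4.58 FPKM. The gene that rose was the glucose transporter gene Slc2a3 (0.66), named after its value was seen, and 2 genes rose without knockout replicate 1.

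Of 19 genes of the integrated stress response, which adjusts translation and amino acid supply, 11 fell and 4 rose, with 11 and 4 adjusted over the list alone (camera adjusted p = 0.00148, and adjusted p = 0.334 with an estimated correlation). The fallen genes with the smallest p encode enzymes of serine synthesis and the folate cycle. Mthfd2 fell from 109 ± 13.4 to 20.7 ± 2.21 FPKM, Psat1 from 212 ± 10.7 to 66.7 ± 6.94 FPKM and Phgdh from 285 ± 6.78 to 90.4 ± 11.6 FPKM. The 4 genes that rose, named after their values were seen, encode transcription factors of the response, namely Atf3 (log2 fold change 2.13), Ddit3 (1.22), Cebpb (0.81) and Atf5 (0.54). The calls of Cebpb with median-ratio scaling and of Cebpb and Atf5 with upper-quartile scaling were lost. Of 12 interferon response genes, 7 fell and 3 rose, with 7 and 3 adjusted over the list alone (camera adjusted p = 0.0738). Zbp1 fell from 5.26 ± 0.487 to 0.103 ± 0.0723 FPKM and Bst2 from 196 ± 13.04 to 93.7 ± 14.0 FPKM, while Isg20 rose from 0.590 ± 0.176 to 3.39 ± 0.650 FPKM. The others that rose, named after their values were seen, were Cxcl10 (2.11) and Ddx58 (0.29), and the Ddx58 call was lost with median-ratio and upper-quartile scaling.

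**Figure D3:**
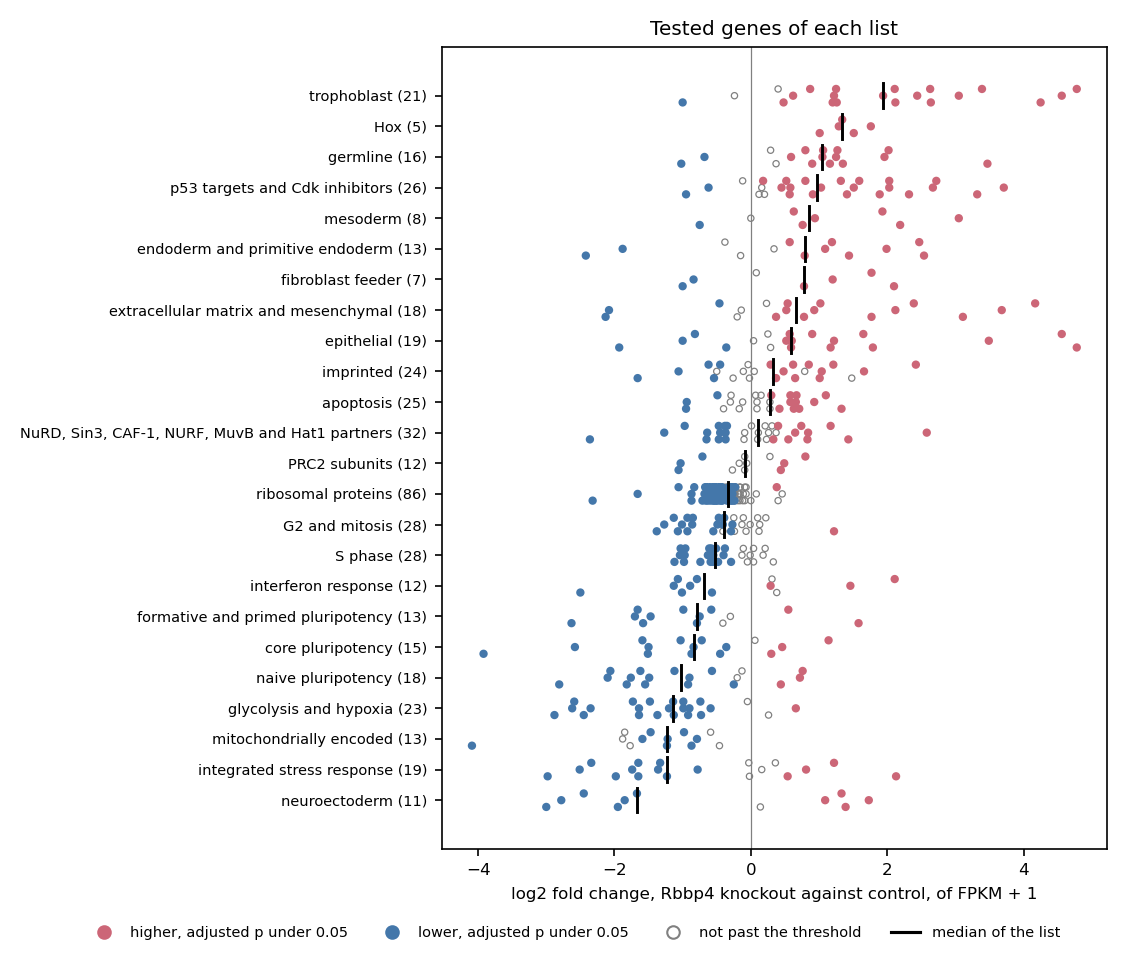
Log2 fold change of FPKM + 1, knockout against control (horizontal axis), of each tested gene in 24 lists (vertical axis, number tested in brackets), with the list median as a bar. Filled points passed an adjusted p of 0.05. The bar lies at 1.94 for the trophoblast list, 1.34 for the Hox list and −1.67 for the neuroectoderm list.

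2 lists taken as signs of RNA quality were lower in the knockout libraries. The core, naive and formative pluripotency, proliferation, glycolysis and integrated stress response lists were lower in the same libraries. The trophoblast, germline, Hox and p53 target lists were higher in them. Of 13 mitochondrially encoded genes, 8 fell, mt-Co2 among them, and none rose, with 9 and 0 adjusted over the list alone (camera adjusted p = 4.69e-04, and adjusted p = 0.287 with an estimated correlation). mt-Nd2 fell from 1217 ± 134 to 411 ± 112 FPKM, mt-Nd6 from 612 ± 30.1 to 231 ± 92.9 FPKM and mt-Nd3 from 617 ± 177 to 262 ± 55 FPKM. At an unadjusted p under 0.05 in limma 0 were higher and 9 lower. Values of other members were erratic within groups, mt-Nd4l being at 0, 121 and 20.1 FPKM in the controls, and mt-Co2, an abundant transcript of all cells, was listed at 0 in knockout replicates 1 and 2, so a 0 in these files can be a failed estimate and the call of mt-Co2 rests on such values. Of 86 ribosomal protein genes, 51 fell and 1 rose, with 53 and 1 adjusted over the list alone (camera adjusted p = 1.25e-10, and adjusted p = 0.334 with an estimated correlation). Rps20 fell from 2692 ± 9.82 to 1484 ± 193 FPKM and Rps25 from 1763 ± 69.2 to 1122 ± 56.5 FPKM, and the germ-cell copy Rpl39l, whose lowest value was 0, had 2.25, 2.73 and 2 FPKM in the controls and 0.07, 0 and 0.07 FPKM in the knockout libraries. The number of fallen ribosomal protein genes was 24, 28 and 23 without control replicate 1, 2 or 3, 24 without knockout replicate 2, 80 with upper-quartile scaling and 27 with equal FPKM sums. It was 25 of 88 without a filter, and with the GC and length correction 33 fell and 4 rose. The 1 that rose, named after its value was seen, was Rpl7l1 (0.38), whose call was lost with median-ratio (0.22) and upper-quartile scaling (0.12). With equal FPKM sums 3 rose, and 0 rose without control replicate 1, 2 or 3 and 2 without knockout replicate 3. Many pseudogene copies of both kinds of gene exist in the nuclear genome, and reads shared with them make single values uncertain.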

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

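Rescaling to equal FPKM sums, the filter of 5 FPKM, the GC and length correction and protein-coding genes alone were chosen after the data were examined. Over all alternatives, 62 values of the gene counts stayed within 1.5 times the value reported, 1353 of the values of named genes kept direction and side of the threshold, and 389 values of list tests did. DESeq2, limma-voom and a count-based filter were not run because the values are not counts, a 1.5-fold test in limma stood in for the edgeR one, and scaling to library size alone equals the deposited FPKM. Against a 1.5-fold change, 1535 genes were higher and 839 lower, fewer because the test asks for more. Upper-quartile scaling moved the genes changed by at least 2-fold to 1172 higher and 1513 lower, a shift its scaling factors bring by construction. All 13 lists called by camera lost the call with an estimated correlation, at adjusted p of 0.209 (core pluripotency), 0.122 (naive pluripotency, S phase, G2 and mitosis), 0.194 (formative and primed pluripotency, Hox, glycolysis and hypoxia), 0.287 (trophoblast, germline, mitochondrially encoded), 0.204 (p53 targets) and 0.334 (integrated stress response, ribosomal proteins), which is a wider null for the same values. Their estimated correlations ran from −0.179 (Hox) to 0.521 (ribosomal proteins), with 0.345 for trophoblast. Where the estimate lies far above the preset 0.01, the camera p-values with the preset may be too small. G2 and mitosis (−0.004) and Hox lost the call with estimates below the preset, and naive pluripotency (0.019) with an estimate near it. With an estimated correlation the test also has fewer degrees of freedom, taken from the libraries. The lost calls therefore do not show that correlation between genes accounts for these list results. Lists that gained a call did so as follows, and the cause was not tested. With median-ratio scaling these were mesoderm (0.0372) and epithelial (0.0387), with upper-quartile scaling mesoderm (0.0353), epithelial (0.0334) and matrix (0.0353), without a filter endoderm (0.0303) and epithelial (0.0147), at 5 FPKM mesoderm (0.0163), neuroectoderm (0.0210) and interferon response (0.0363), and with equal FPKM sums interferon response (0.0351). The fry test, which makes no comparison with other genes, gave adjusted p of 6.13e-05 (mesoderm), 2.46e-04 (endoderm and interferon response), 0.00217 (neuroectoderm), 5.60e-04 (apoptosis), 0.00177 (imprinted), 2.43e-04 (matrix), 4.16e-04 (fibroblast) and 0.00170 (epithelial). Directions of lists not called by camera turned for the complex partners with fry (0.0226), for neuroectoderm without a filter (0.637), for imprinted genes at 5 FPKM (0.971) and with the GC and length correction (0.953), and for fibroblast genes at 5 FPKM (0.853), with the cause not tested. With 1 library left out, camera adjusted p ranged from 0.0410 to 0.0877 for mesoderm and from 0.0339 to 0.0746 for epithelial genes. Cphx1, not called, turned to 0.08 with a pseudocount of 0.1, and ranged from −0.68 to 0.32 with 1 library left out, being positive without control replicate 1 (0.24), control replicate 2 (0.08) or knockout replicate 2 (0.32). With the replicate number as a block 4872 genes were higher and 2907 lower. Same-numbered libraries did not deviate together (correlations across genes of −0.001, −0.009 and 0.049), and only replicate 3 correlated best with its own number, so the numbers were not taken to pair libraries. The block changed no call of the lists. The pseudocount of 1 shrinks fold changes of genes near 1 FPKM. For the 5 tested Hox genes the median log2 fold change was 1.34 with it and 2.92 with a pseudocount of 0.1.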

Other observations

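Further gene groups were looked at only after the data had been examined, with 8 lists chosen from what had been seen, so their counts describe these libraries and are not independent evidence. Of 26 genes of the actin cytoskeleton and targets of serum response factor, 25 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.84e-08 over the 8 lists, and adjusted p = 0.362 with an estimated correlation). Tagln rose from 15.8 ± 6.995 to 203 ± 41.4 FPKM and Tgfb1i1 from 0.787 ± 0.235 to 29.5 ± 1.96 FPKM, while Actb, the member that did not pass, had 1931 ± 200 and 1943 ± 84.8 FPKM. Of 21 immediate early genes and AP-1 subunits, 18 rose and 1 fell, with 19 and 1 adjusted over the list alone (camera adjusted p = 8.71e-06, and adjusted p = 0.116 with an estimated correlation), among them Jun, from 7.33 ± 0.529 to 38.4 ± 4.07 FPKM, and Fosl1, from 2.47 ± 0.757 to 18.97 ± 0.7503 FPKM. Of 8 tested markers of later trophoblast subtypes, 6 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0158, and adjusted p = 0.410 with an estimated correlation), and Slco2a1 rose from 0.820 ± 0.286 to 12.1 ± 2.34 FPKM. 16 markers of that list stayed below the filter, and without a filter 7 of 18 were higher, with a median log2 fold change of 0.29 instead of 1.27 (camera adjusted p = 0.0305). At an unadjusted p under 0.05 in limma 0 genes of the actin list and 0 of the later trophoblast list were lower.

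Cholesterol synthesis genes fell together, 19 of 23, with 1 higher, the same numbers as adjusted over the list alone (camera adjusted p = 1.84e-08, and adjusted p = 0.410 with an estimated correlation). Dhcr7 fell from 76.6 ± 13.1 to 11.1 ± 2.45 FPKM. Insig1, which encodes a regulator of the pathway and not an enzyme of it, fell from 46.2 ± 10.01 to 9.94 ± 2.37 FPKM. Of 15 genes of Nodal signalling, 7 fell and 5 rose (camera adjusted p = 0.118), but 7 fell and 8 rose without knockout replicate 1, and 3 rose with upper-quartile scaling. The feedback inhibitor genes Lefty1 and Lefty2 fell from 97.4 ± 11.1 to 8.59 ± 0.765 FPKM and from 102 ± 12.5 to 12.02 ± 1.03 FPKM. Of 30 nuclear-encoded genes of the respiratory chain 11 fell and 1 rose, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.0189, and adjusted p = 0.511 with an estimated correlation). With equal FPKM sums 6 fell and 6 rose, and the respiratory chain list then did not pass (camera adjusted p = 0.158), nor with the GC and length correction (0.233) or without knockout replicate 3 (0.0647). It had 6 fallen genes without control replicate 1, 2 or 3 and 18 with upper-quartile scaling, and 3 risen genes without knockout replicate 1 and 2 without knockout replicate 3. Annexin genes (5 of 9 higher, 1 lower, camera adjusted p = 0.178) and lysosomal genes (13 of 23 higher, 5 lower, camera adjusted p = 0.118) did not pass, although Anxa3 rose from 9.61 ± 1.39 to 153 ± 19.7 FPKM.

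Of the tests that follow, the rescaling without abundant genes and the GC and length correction of the trophoblast list were set down before their results were seen, and the others after. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 4978 genes in the larger direction and 3051 in the smaller, and 1821 and 967 changed by at least 2-fold, and in each case 1 of the 10 splits, the real one, reached that number. The highest of the other splits gave 3 genes in the larger direction and 0 in the smaller, both at any size and at 2-fold or more. Each other split mixes control and knockout libraries, so the group difference enters its spread and low counts follow by construction. The counts of these splits therefore do not test chance.

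More genes were higher than lower, and 2 technical explanations stay open. The 500 most abundant genes made up 46.7% of the length-weighted signal in the controls and 38.7% in the knockout libraries, and after rescaling on length-weighted totals the median log2 fold change of all tested genes was 0.22 with every gene in the total and 0.045 with these left out, against 0.17 with the values as deposited. The excess may therefore come from scaling to a total in which abundant transcripts fell. Over 9 bins of GC content and transcript length, the share of called genes that were higher ran from 46.7% among short GC-rich transcripts to 80.8% among long GC-poor ones. The correction for both left 61.7% of calls higher, but it kept the median of each library and so cannot decide, and whether the trend is technical or a property of the genes that respond to the knockout was not tested.

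Knockout replicate 1 held 21.3 FPKM of Rbbp4, against 12.7 and 11.1 FPKM, which would take 19.9% of control cells if it were a mixture. The 105 genes that were lower by at least 4-fold in the other knockout libraries implied a median of 7% (upper quartile 12.2%). Genes chosen in the same way gave −1.7% for replicate 2 and −2.9% for replicate 3. The 7% argues against unchanged control cells as the whole source, but not against a smaller share of them. A candidate explanation is that the cells of this library were less far along the same change. The 183 genes higher by at least 4-fold in the other libraries were missing a median of 29% of their change in replicate 1. The quartiles of these risen genes, 11.4% and 46.8%, also enclose the 19.9% of a mixture. The same measure gave −11.5% for replicate 2 and −8.4% for replicate 3. The labels give no time since deletion, so this remains a hypothesis.

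The rise of trophoblast genes was set against 3 technical explanations. After the GC and length correction, 18 of the 21 genes were still higher, which argues against that trend as the whole cause. If differentiated cells made no pluripotency transcripts beside a remainder of unchanged stem cells, these genes would be left at about the level of Nanog, at most 6.48% of control. 27 of the other 32 tested core and naive genes stayed above 3 times that share, but some of these were above control, up to 325.6% (Tbx3). Differentiated cells that made some of these transcripts would give the same, so the test cannot decide on a mixture. Fibroblast feeder cells bring abundant collagen transcripts, but Col1a1, Col1a2 and Col3a1 summed to 1.05 FPKM in the knockout libraries. Fn1 fell, but the controls held 162 FPKM of it with each of these collagens below 1 FPKM. The fall of Fn1 therefore does not bear on feeder cells. A change of the stem cells toward a trophoblast-related program with partly retained pluripotency transcripts may be proposed as a hypothesis. It was found and tested on the same 6 libraries, and cells of mixed identity cannot be separated in bulk RNA. The hypothesis is limited, since Elf5 and Fgfr2 of the trophoblast list were not called and Cdh3 fell. The germline, Hox and p53 target lists rose as well. Of the mesoderm genes 6 of 8 rose and 1 fell, and of the endoderm genes 8 of 13 rose and 2 fell. Neither the mesoderm nor the endoderm list passed with camera.

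No chromosome showed a shift of the size that an extra copy in all knockout cells would give. Median log2 fold changes of protein-coding genes, relative to all of them, ran from −0.18 on chromosome 7 to 0.12 on chromosomes 3 and 18, where an extra copy would give 0.585.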
